A study of Rattus norvegicus with 42 samples.

How the data were processed

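PolyA RNA of rat retina was sequenced as paired 150 bp reads, with 6 groups of animals as biological replicates, per the labels. The deposited file holds raw counts per gene, not normalised by the authors as far as the values show: all values are whole numbers of at least 0 and the totals differ between libraries. Per the submitters' processing notes, the tools used on the reads were Trimmomatic 0.39, STAR 2.7.9a, featureCounts from Subread 2.0.1, DESeq2 1.30.1 and R 4.0, with the rn6 genome build. The strand setting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Genes are named by the symbols that the file pairs with its Ensembl identifiers. A number added to the end of the name marks 4504 genes that carry the name of another, and such genes, like members of multigene families, can share reads, so their values are uncertain.

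Counts were analysed for 31 of the 42 labelled samples, all with a column that matched 1 sample. The remaining 11 were not analysed here. Of 32623 genes in the file, 9389 had 0 counts in every library. The filter of edgeR (filterByExpr with a minimum count of 10 and a minimum total of 15, on the groups) kept 18094 genes and left out 14529. Total counts lay between 25158407 and 182162368 per library, with a median of 106887932.

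Each comparison was tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM scaling, 1 coefficient per group, all 31 libraries in 1 fit, no covariate) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the 18094 genes. A gene was called at an adjusted p under 0.05. There were 9 pairwise comparisons and 2 interactions, each a test of whether the response to light differed between 2 treatments. Log2 fold changes are given with their standard error (SE). An adjusted p in the text comes from this test unless another is named. Fits of the 2 groups alone or with another tool were alternatives.

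The comparisons, the test, the gene lists and the rule for the genes named were chosen before the data were examined. The rule took, for each comparison, the 5 highest and the 5 lowest log2 fold changes among called genes with a proper symbol and a mean log2 CPM (library-scaled counts) of at least 1, or, where no gene passed, the 5 genes with the smallest unadjusted p. It added the 2 members of each gene list with the smallest adjusted p, and, among others, the genes Gnat1, Opn1sw, Gfap, Edn2, Ccl2, C3, Hmox1 and Sod2 in all comparisons. The text gives a selection in that order. Further genes are said to have been chosen after their values were seen.

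A total of 38 gene lists with 793 members, 28 of them without a match in the file, were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. Alternatives were fry and camera on ranks. Beside the members called over all genes, the text gives the number called when the p-values were adjusted over the list alone.

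A light response score was built from the uninjected groups alone, as the mean log2 CPM of genes raised by light minus that of genes lowered by light, both at an adjusted p under 0.05 and at least 2-fold, each gene centred over those groups. A rod score was the mean log2 CPM of the rod phototransduction list. Log2 CPM had a prior count of 2. Scores were compared with 2-sided exact permutation tests, whose 95% intervals were obtained by inverting the test, and the interaction was tested with 100000 permutations. P-values were adjusted within each family of score comparisons. The mean log2 CPM of 12 lists was compared in the same way in 7 comparisons, 84 tests chosen after the results were seen.

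Fits were tested on simulated data, with 200 of 18094 genes changed by a known fold, drawn from genes above a minimum level. Counts were drawn from the mean of each gene over all libraries, its spread and the real library sizes, each gene independently. Variation that libraries share across genes and the near-identical pairs of libraries were not simulated, so the share called in the real data may be lower. For nanoceria plus light against vehicle plus light, 61.2% of the genes changed 1.5-fold, 85.1% of those changed 2-fold and 97% of those changed 4-fold were called, with 6 false calls. For light damage against control the shares were 58.2%, 79.1% and 98.5% with 8 false calls, and for nanoceria against vehicle 53.7%, 85.1% and 100% with 8 false calls.

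The alternatives were the size factors of DESeq2 1.42.0 or library size alone in place of TMM, no filter on low counts, only the libraries of the groups compared, the Wald test of DESeq2, limma-voom with sample quality weights, the replicate number as a block, and leaving out every library with a given replicate number. For the scores, a prior count of 0.5 and the median over genes were also tried. Leaving out each library alone, summing each of 2 near-identical pairs of libraries to 1, limma-voom on those sums, and a term for sex inferred from Y-linked genes were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.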

Results

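Retinal gene expression was measured in rats of 6 groups, to ask how damaging light changes the retina and whether nanoceria, cerium oxide nanoparticles that take up reactive oxygen species, alter that change. Rats were left untreated (control), were exposed to light of 15000 lux for 24 h (light damage), received vehicle in the vitreous of the eye without or with that light, or received 1 mM nanoceria there without or with that light. Counts were analysed for 5 control, 7 light damage, 5 vehicle, 5 vehicle plus light, 4 nanoceria and 5 nanoceria plus light libraries. Total counts per library were 74306775 to 120222710 in control, 25158407 to 149429413 in light damage, 73369026 to 121336562 in vehicle, 87979270 to 182162368 in vehicle plus light, 83372000 to 113801610 in nanoceria and 97980166 to 120285482 in nanoceria plus light. Y-linked transcripts were high in 4 of 5 control, 4 of 7 light damage, 1 of 5 vehicle, 2 of 5 vehicle plus light, 2 of 4 nanoceria and 3 of 5 nanoceria plus light libraries, so the sexes were unevenly spread. The first 3 principal components held 20.8%, 12.7% and 7.04% of the variance.

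Light without injection, 7 light damage against 5 control libraries, lowered 30 of 32 measured genes of rod phototransduction and raised genes of glial reactivity and of cytokine signalling. Rod transducin, Gnat1, changed by -3.06 ± 0.38 (log2, SE). Reep6, which rods need to traffic membrane proteins, changed by -2.88 ± 0.28, and Esrrb, a nuclear receptor that keeps rods alive, by -2.47 ± 0.38. These 3 had edgeR adjusted p from 1.44e-08 to 2.42e-05. Of 32 measured rod genes, 30 fell and none rose (30 when adjusted over the list alone; adjusted p = 0.23 with an estimated correlation). The short-wave cone opsin Opn1sw did not pass (-0.56 ± 0.35, edgeR adjusted p = 0.272), and of 14 cone genes 2 rose and 1 fell (2 and 4 adjusted over the list alone). Rpe65, which makes the chromophore of the opsins, changed by -1.54 ± 0.29. Ndufa10l1, whose symbol is that of a copy of a subunit of respiratory complex I and which can share reads with it, changed by -3.97 ± 1.07 (edgeR adjusted p = 0.00718). Its level was high in some and low in other libraries of the injected groups (6.52 ± 5.54 CPM, SD, n = 5, in vehicle), so it varied between animals without light.

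Among the genes that rose with light, the monocyte attractants Ccl2 (6.69 ± 0.47), Ccl3 (5.93 ± 0.38) and Ccl7 (5.84 ± 0.49) and the T-cell attractant Cxcl10 (5.27 ± 0.56) had the largest changes of the named genes. Ptx3, a soluble pattern recognition protein, rose by 5.13 ± 0.75, the AP-1 factor Fosl1 by 4.86 ± 0.35, the survival cytokine Lif by 4.67 ± 0.47 and Socs3, an inhibitor of cytokine signalling, by 4.49 ± 0.27. The adhesion molecule Icam1 rose by 2.78 ± 0.18 and the transcription factor Stat3 by 1.84 ± 0.13. Edn2, an endothelin made by stressed photoreceptors, rose by 3.74 ± 0.42, Fgf2 by 2.23 ± 0.17 and Gfap, the intermediate filament of reactive glia, by 1.99 ± 0.50 (edgeR adjusted p = 0.00383). Of 24 glial reactivity genes 20 rose (21 adjusted over the list alone; adjusted p = 0.00567 with an estimated correlation), and of 26 chemokine and cytokine genes 15 rose (17 adjusted over the list alone; adjusted p = 0.027 with an estimated correlation). Of 18 NF-kB targets 12 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation). Complement C3 rose by 1.41 ± 0.46 (edgeR adjusted p = 0.0254), a call that ended without control 1, 2 or 5 or without light damage 3 (edgeR adjusted p from 0.0536 to 0.116). Of 22 complement genes 12 rose (13 higher and 2 lower adjusted over the list alone; adjusted p = 0.318 with an estimated correlation). The interferon factor Irf9 rose by 1.70 ± 0.13 and the antiviral Oas1b by 2.05 ± 0.19, with 16 of 35 interferon genes higher and 1 lower (21 and 1 adjusted over the list alone; adjusted p = 0.361 with an estimated correlation). Of 25 microglia and macrophage genes 12 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.392 with an estimated correlation).

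Single genes of oxidative and other stress responses rose with light as well. Heme oxygenase Hmox1, which breaks down heme, rose by 3.87 ± 0.38, the metal-binding Mt2A by 3.68 ± 0.32 and the mitochondrial superoxide dismutase Sod2 by 1.43 ± 0.15. The stress factor Atf3 rose by 2.57 ± 0.26 and the amino acid response enzyme Asns by 1.71 ± 0.12. Of 33 antioxidant and NRF2 target genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.684 with an estimated correlation). Of 26 genes of the integrated stress and unfolded protein response 12 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation), and of 25 cell death genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.236 with an estimated correlation). Hk2, the hexokinase of photoreceptors, changed by -1.63 ± 0.21, the lactate transporter Slc16a1 by -0.96 ± 0.11 and the glutamine synthetase of Müller glia, Glul, by -0.93 ± 0.12. Of 21 sterol synthesis genes 15 fell (18 adjusted over the list alone; adjusted p = 0.305 with an estimated correlation). Of 21 glycolysis genes 10 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.359 with an estimated correlation). In all, edgeR called 2147 genes higher and 1927 lower, of which 635 and 229 changed at least 2-fold. With library size alone as the scaling, 2371 were higher and 1100 lower. Of the markers of tissue outside the retina, 1 of 7 blood genes rose (1 adjusted over the list alone) and of 12 ciliary body and iris genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), with neither list past the threshold of camera.

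**Figure D1:**
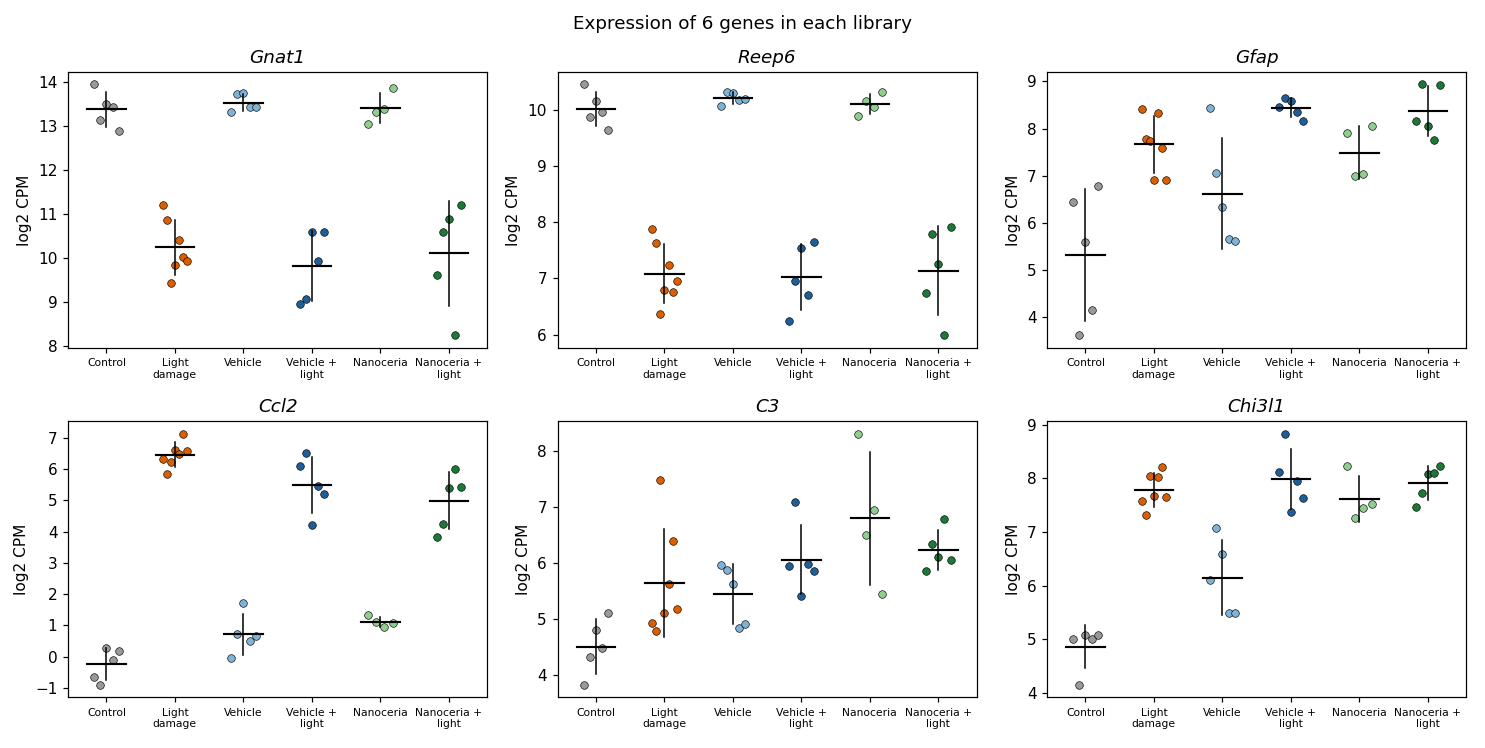
Log2 CPM of Gnat1, Reep6, Gfap, Ccl2, C3 and Chi3l1 in each library (points) by group, with the group mean (horizontal line) and SD (vertical line). Gnat1 is lower, and Ccl2 higher, in the 3 light-exposed groups than in the 3 groups kept without that light.

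Light after vehicle, 5 vehicle plus light against 5 vehicle libraries, lowered 27 of 32 rod genes and 7 of 14 cone genes, and raised genes of glial reactivity and stress responses and 14 of 26 chemokine and cytokine genes. Gnat1 changed by -3.55 ± 0.44, Reep6 by -3.10 ± 0.32 and the cone transducin Gnat2 by -0.93 ± 0.17. Of 32 rod genes 27 fell (31 adjusted over the list alone; adjusted p = 0.266 with an estimated correlation), and of 14 cone genes 7 fell and 2 rose (7 and 2 adjusted over the list alone; adjusted p = 0.496 with an estimated correlation). Opn1sw fell by 1.21 on the log2 scale (SE 0.38, edgeR adjusted p = 0.0274), a call that ended without vehicle 1, 2 or 3 or vehicle plus light 1, 2 or 4 (edgeR adjusted p from 0.0625 to 0.0843). Among genes that rose were Ccl2 (4.88 ± 0.44), Ccl7 (4.80 ± 0.47), Ptx3 (4.68 ± 0.74), Cxcl10 (4.34 ± 0.54), Lif (4.09 ± 0.46), Socs3 (4.08 ± 0.27), Edn2 (3.45 ± 0.42) and the stress hormone Gdf15 (3.61 ± 0.28). Asns rose by 2.14 ± 0.13, Irf9 by 1.54 ± 0.14, Sox9, a transcription factor of Müller glia, by 1.15 ± 0.19, Hmox1 by 2.90 ± 0.38, Mt2A by 3.11 ± 0.32 and Sod2 by 1.14 ± 0.15, while Hk2 changed by -1.74 ± 0.24. Neither Gfap (1.41 ± 0.51, edgeR adjusted p = 0.0573) nor C3 (0.66 ± 0.47, edgeR adjusted p = 0.4) passed. With libraries or a replicate number left out, Gfap ranged from 1.2 to 2.16, the highest without vehicle 1, and was called in 2 of 17 such fits.

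Of 24 glial reactivity genes 19 rose after vehicle and light (20 adjusted over the list alone; adjusted p = 0.00706 with an estimated correlation), as did 16 of 26 genes of the integrated stress and unfolded protein response, with 2 lower (18 and 3 adjusted over the list alone; adjusted p = 0.017 with an estimated correlation). Of 26 chemokine and cytokine genes 14 rose (14 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), and of 35 interferon genes 19 (24 adjusted over the list alone; adjusted p = 0.327 with an estimated correlation). Antioxidant and NRF2 targets rose in 8 of 33 cases (8 adjusted over the list alone; adjusted p = 0.496 with an estimated correlation), and 11 of 21 glycolysis genes fell (13 lower and 1 higher adjusted over the list alone; adjusted p = 0.327 with an estimated correlation). Lens genes fell in 4 of 20 cases (11 adjusted over the list alone; adjusted p = 0.624 with an estimated correlation), among them the crystallin Cryga (-3.69 ± 1.16, edgeR adjusted p = 0.0267) and the lens water channel Mip (-3.05 ± 1.01, edgeR adjusted p = 0.0366). Without vehicle 1 the change of Cryga was -0.97 with an edgeR adjusted p of 0.554. Its call also ended without vehicle plus light 2, 3, 4 or 6 (edgeR adjusted p of at least 0.0505), and that of Mip without vehicle 1, 2 or 3 or any library of vehicle plus light (edgeR adjusted p from 0.0506 to 0.104). Lens genes held 1.42% ± 1.23 (SD, n = 5) of the counts of vehicle libraries and 0.345% ± 0.316 (SD, n = 5) of those of control; without vehicle 1 the first was 0.914%, and without control 5 the second was 0.209%. Counts came to 1749 higher and 1297 lower, with 435 and 241 at least 2-fold. With library size alone, 2434 genes were higher and 688 lower, and the median of all genes moved from 0.0207 to 0.115.

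Light after nanoceria, 5 nanoceria plus light against 4 nanoceria libraries, also lowered 27 of 32 rod genes and raised genes of glial reactivity and stress responses and 12 of 26 chemokine and cytokine genes. Gnat1 changed by -3.01 ± 0.44, Reep6 by -2.82 ± 0.32, Esrrb by -2.30 ± 0.44 and Tmem116, a membrane protein of little known function, by -2.63 ± 0.34. Of 32 rod genes 27 fell (31 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation). The largest increases among named genes were those of Lif (4.26 ± 0.51), Ccl2 (4.07 ± 0.46), Fosl1 (3.94 ± 0.37), Atf3 (3.88 ± 0.31), Cxcl10 (3.70 ± 0.58) and Socs3 (3.60 ± 0.28). Edn2 rose by 2.91 ± 0.44, Hmox1 by 2.75 ± 0.41, Mt2A by 3.22 ± 0.35, Sod2 by 1.16 ± 0.16, Asns by 1.95 ± 0.13 and Irf9 by 1.53 ± 0.15. Hk2 changed by -1.90 ± 0.25 and P2ry12, the ADP receptor of resting microglia, by -1.30 ± 0.26 (edgeR adjusted p = 0.000787). Opn1sw (-0.81 ± 0.40, edgeR adjusted p = 0.193), Gfap (0.87 ± 0.54, edgeR adjusted p = 0.326) and C3 (-0.90 ± 0.50, edgeR adjusted p = 0.261) did not pass. Without light, C3 was already higher, and Atf3 and Atf4 lower, in nanoceria than in control, as given below. The changes of these genes with light start from that level.

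After nanoceria and light, 20 of 26 genes of the integrated stress and unfolded protein response rose and 1 fell (23 and 3 adjusted over the list alone; adjusted p = 0.00669 with an estimated correlation), and 16 of 24 glial reactivity genes rose (19 adjusted over the list alone; adjusted p = 0.0114 with an estimated correlation). Of 26 chemokine and cytokine genes 12 rose (13 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation), of 22 immediate early genes 15 (16 adjusted over the list alone; adjusted p = 0.224 with an estimated correlation) and of 33 antioxidant and NRF2 targets 7 (7 adjusted over the list alone; adjusted p = 0.49 with an estimated correlation). Vascular genes fell in 5 of 18 cases and rose in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.414 with an estimated correlation). Microglia and macrophage genes went both ways, 4 higher and 4 lower of 25 (5 and 5 adjusted over the list alone). edgeR called 1474 genes higher and 1046 lower, with 324 and 236 at least 2-fold. With the size factors of DESeq2, 1115 were higher and 1306 lower, and with library size alone 1480 and 671. Fitted on these 2 groups alone, the total was 1107.

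The 3 responses to light, which share no libraries, were set side by side. Of the genes tested, 920 rose and 670 fell in all 3, among them Gnat1, Ccl2, Hmox1 and Sod2, and 3 were called in all 3 with differing directions. Light damage against control and vehicle plus light against vehicle had 1281 higher and 974 lower genes in common, where independent lists would share 207.5 and 138.1. For nanoceria plus light against nanoceria, the numbers shared with the uninjected response were 999 and 761 (174.9 and 111.4 for independent lists), and with the response after vehicle 1142 and 778 (142.5 and 75).

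Injection of vehicle without light, 5 vehicle against 5 control libraries, changed few genes. Etv4, an ETS factor downstream of growth factor signalling, changed by -1.02 ± 0.14 (edgeR adjusted p = 0.000994) and the smooth muscle actin Actg2 by -2.42 ± 0.45 (edgeR adjusted p = 0.0452). Il17rb, a receptor of the interleukin 17 family, rose by 1.62 ± 0.27 (edgeR adjusted p = 0.0186) and LOC497796, named after its value was seen, by 1.92 ± 0.34 (edgeR adjusted p = 0.0343). Gfap (1.26 ± 0.51), Ccl2 (1.00 ± 0.42) and C3 (0.95 ± 0.48) did not pass. No member of any list was called over all genes. The microglia and macrophage list had a median change of 0.39 (adjusted p = 0.369 with an estimated correlation) and the complement list of 0.40 (adjusted p = 0.317 with an estimated correlation), with 0 members adjusted over the list alone in both. Lens genes had a median of 2.39, and 15 of 20 passed adjusted over the list alone (adjusted p = 0.317 with an estimated correlation).

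The 4 calls of vehicle against control, 2 higher and 2 lower, stood against 1462 genes at an unadjusted p under 0.05, where 905 are expected by chance. With either other scaling, 2 genes were higher and 1 lower. DESeq2 called 51 genes and limma-voom 2211, but limma-voom called 12 once each near-identical pair of libraries was summed. The number was 24 without vehicle 1, 7 without control 1, 2 without vehicle 7, and 1 without control 2, control 4 or vehicle 2. Actg2 lost its call without control 2, 4 or 6 or vehicle 2, 3 or 7 (edgeR adjusted p up to 0.195), Il17rb without control 2, control 4 or vehicle 2 (up to 0.136), and LOC497796 without control 1, 2, 4 or 6 or vehicle 2 or 7 (up to 0.16). These 3 also lost their call with a term for sex, where Etv4 alone stayed called. Y-linked transcripts were high in 4 of 5 control and 1 of 5 vehicle libraries, so sex and injection are partly mixed in this comparison.

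Nanoceria without light, 4 nanoceria against 5 control libraries, raised genes of microglia, complement and lymphocytes and lowered 5 of 26 stress response and 5 of 21 sterol synthesis genes; the injection itself is part of this contrast. Chi3l1, a secreted protein of reactive astrocytes and macrophages, rose by 2.76 ± 0.31, Il17rb by 2.57 ± 0.29, the chemokine Cxcl11 by 2.46 ± 0.37, the granulocyte receptor Csf3r by 2.13 ± 0.46 and the Fc receptor Fcgr3a by 2.03 ± 0.34. The oxidase subunit Cybb (1.20 ± 0.22), the microglial Aif1 (1.13 ± 0.21) and the complement genes C1qa (1.247 ± 0.24) and C1qb (1.14 ± 0.22) rose too, with the chemokine Ccl4 (1.81 ± 0.38), ceruloplasmin Cp (1.44 ± 0.19) and Fgf2 (1.03 ± 0.18). C3 rose by 2.60 ± 0.51 (edgeR adjusted p = 0.00613), and without nanoceria 1 by 1.85 (edgeR adjusted p = 0.0585). The T-cell receptor chains Cd3d (2.14 ± 0.47) and Cd3e (2.04 ± 0.43) were low in level (0.447 and 1.49 CPM in nanoceria) and passed with all libraries but not without nanoceria 3 (edgeR adjusted p = 0.0876 and 0.0821). Trib3 (-1.71 ± 0.31) and Atf4 (-0.46 ± 0.09), both of the integrated stress response, fell, as did Mvd (-0.51 ± 0.10) of sterol synthesis and Actg2 (-2.50 ± 0.49). Atf3 (-1.18 ± 0.28), the mitochondrial folate enzyme Mthfd2 (-1.10 ± 0.27) and the pheromone receptor Vom2r44 (-2.42 ± 0.59) were called too. The call of Atf3 ended without control 4 or 5 or nanoceria 2 (edgeR adjusted p up to 0.0891), that of Mthfd2 without control 5 or nanoceria 2, 3 or 5 (up to 0.0891), and that of Vom2r44 without control 2 or any nanoceria library (up to 0.0736). Without replicate 1 of every group, Csf3r, Cybb, C1qa, C1qb, C3, Ccl4, Cd3d, Cd3e, Atf4, Mvd, Actg2 and Mthfd2 did not pass (edgeR adjusted p from 0.0501 to 0.139).

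Of 25 microglia and macrophage genes 15 rose with nanoceria (17 adjusted over the list alone), as did 10 of 22 complement genes (15 adjusted over the list alone), 3 of 13 T and B lymphocyte genes (11 adjusted over the list alone) and 2 of 8 neutrophil genes (4 adjusted over the list alone). For each of these 4 lists, camera gave an adjusted p of 0.0497 with an estimated correlation. The mean log2 CPM of each list had an exact permutation p of 0.00794, the smallest it can give, and 0.0741 adjusted over 84 list tests. Of 18 vascular genes 1 rose (5 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation), with a mean log2 CPM higher by 0.36 (95% interval 0.16 to 0.54, exact permutation p = 0.0159, adjusted p = 0.0954). The endothelial Vwf, called here, lost its call without control 1, 2 or 5 or nanoceria 1, 2 or 3 (edgeR adjusted p from 0.057 to 0.11). Of 24 glial reactivity genes 3 rose (8 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation). Of 26 genes of the integrated stress and unfolded protein response 5 fell (7 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation), and of 21 sterol synthesis genes 5 fell (18 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation). No rod gene and none of 33 antioxidant and NRF2 targets was called by edgeR. Hmox1 (0.38 ± 0.37, edgeR adjusted p = 0.66), Sod2 (-0.10 ± 0.16, 0.799), Ccl2 (1.30 ± 0.43, 0.115), Edn2 (1.48 ± 0.44, 0.0715) and Gfap (1.79 ± 0.53, 0.0722) did not pass. With libraries or a replicate number left out, Edn2 ranged from 0.827 to 1.95 and Gfap from 1.36 to 2.23. Each was called in 2 of 16 such fits. edgeR called 313 genes higher and 132 lower, with library size alone 341 and 34, and with the size factors of DESeq2 358 and 88. The total of 445 became 44 without replicate 1 of every group, 251 without control 2, 293 without control 4, 205 without nanoceria 1, 236 without nanoceria 2 and 227 without nanoceria 3. It became 184 with the replicate number as a block. DESeq2 called 713 and limma-voom 1276.

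Nanoceria against vehicle without light, 4 against 5 libraries, is the contrast of particles with the injection held constant. The 5 genes with the smallest p were Nog, an inhibitor of bone morphogenetic proteins (1.97 ± 0.36), the activity-dependent factor Npas4 (-1.67 ± 0.33), the leukocyte receptor Cd84 (1.2505 ± 0.25), the membrane lectin Chodl (0.85 ± 0.18) and Chi3l1 (1.38 ± 0.30), with edgeR adjusted p from 0.133 to 0.227. C3 (1.65 ± 0.50, edgeR adjusted p = 0.425), Gfap (0.53 ± 0.53), Ccl2 (0.30 ± 0.42) and the endothelial genes Vwf (0.69 ± 0.18) and Plvap (0.74 ± 0.21) did not pass. Over all genes no list had a called member. Of 25 microglia and macrophage genes 11 were higher adjusted over the list alone (adjusted p = 0.115 with an estimated correlation), of 13 T and B lymphocyte genes 5 (adjusted p = 0.0481 with an estimated correlation) and of 18 vascular genes 7 (adjusted p = 0.0481 with an estimated correlation). The mean log2 CPM of the lymphocyte list was higher by 0.76 (exact permutation p = 0.0238, adjusted p = 0.105, and p = 0.0571 with the near-identical vehicle pair averaged). That of the vascular list was higher by 0.37 (exact permutation p = 0.0159, adjusted p = 0.0954, and p = 0.0286 with the pair averaged). Fry, which asks whether a list moves on balance in 1 direction, gave an adjusted p of 0.0617 for the vascular and the lymphocyte list. The lens list had a median of -1.61 here (adjusted p = 0.449 with an estimated correlation).

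edgeR called 0 genes between nanoceria and vehicle, with 1021 at an unadjusted p under 0.05 and 905 expected by chance. DESeq2 called 35. With sample quality weights, limma-voom called 1493, and 0 once each near-identical pair of libraries was summed. Leaving out vehicle 2 gave 3 calls (Vwf, Chi3l1 and Serpine3), leaving out nanoceria 2 gave 1 (Nog) and leaving out nanoceria 5 gave 2 (Nog and Cd84). Serpine3 was named after its value was seen.

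Under light, injected and uninjected eyes differed in few genes. Vehicle plus light, 5 libraries, against light damage, 7 libraries, had higher Sox9 (0.95 ± 0.17), Grin3b, a subunit of glutamate receptors (0.62 ± 0.11), Spice1, a centriole protein (0.46 ± 0.07), and Vps50, of endosome recycling (0.37 ± 0.06). The kinetochore gene Zwint (-1.09 ± 0.19), the lysosomal sulfatase Galns (-1.03 ± 0.18) and Apln, a peptide of vessel growth (-0.92 ± 0.16), were lower; these 7 had edgeR adjusted p from 0.00322 to 0.0093. With a replicate number left out of every group, the call ended for Apln without 1, 4 or 6 (edgeR adjusted p up to 0.104), Grin3b without 1 or 6 (up to 0.068). It also ended for Galns without 6 (0.0951), Vps50 without 6 (0.056), Sox9 without 2 (0.0567) and Zwint without 4 (0.0698). Also called were Rpp38 (0.52 ± 0.10), Fkbpl (0.35 ± 0.07) and Wdr91 (-0.58 ± 0.11). Rpp38 lost its call without light damage 1 or vehicle plus light 1 (edgeR adjusted p up to 0.0648), Wdr91 without light damage 3 or 5 or vehicle plus light 1, 3 or 6 (up to 0.0972), and Fkbpl without light damage 1, 3, 5, 6 or 7 or any vehicle plus light library (up to 0.137). The class I histocompatibility genes RT1-CE16_2 (-2.04 ± 0.31), RT1-CE6 (-1.55 ± 0.24) and RT1-CE3 (-1.998 ± 0.39) were lower, but these close copies can share reads and vary between animals, and RT1-CE3 lost its call without vehicle plus light 1, 2 or 3 (edgeR adjusted p up to 0.0878). RT1-CE16_2 held 0.62 to 1.94 CPM in control, 0.59 to 1.75 in vehicle plus light and 1.66 to 6.83 in light damage. RT1-CE6 and RT1-CE3 were also highest in light damage. edgeR called 11 genes higher and 11 lower (DESeq2 92, limma-voom 229). Ccl2 did not pass (-0.80 ± 0.35, edgeR adjusted p = 0.549).

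Nanoceria plus light, 5 libraries, against light damage, 7 libraries, had higher Vps50 (0.40 ± 0.06), Spice1 (0.36 ± 0.07) and the fatty acid transporter Slc27a1 (0.44 ± 0.09). Ghdc (-1.36 ± 0.18, edgeR adjusted p = 0.00089), of little known function, Tigar, a regulator of glycolysis (-0.43 ± 0.09), RT1-CE16_2 (-2.20 ± 0.31), RT1-CE6 (-1.68 ± 0.24) and RT1-CE3 (-2.08 ± 0.39) were lower. The calls of Slc27a1, Spice1 and Tigar, all at an edgeR adjusted p of 0.0388, each ended without any of 9, 10 and 9 single libraries (edgeR adjusted p up to 0.142, 0.164 and 0.164); the highest followed the removal of nanoceria plus light 2 for Slc27a1 and of nanoceria plus light 1 for the other pair. RT1-CE3 lost its call without light damage 4, 5 or 7 or nanoceria plus light 2 (up to 0.0578). Vps50 lost it without replicate 2 of every group (0.0698). Ccl2 did not pass (-1.31 ± 0.35, edgeR adjusted p = 0.197). edgeR called 5 genes higher and 6 lower, and with the size factors of DESeq2 3 and 6. The total was 47 without nanoceria plus light 4, 6 without nanoceria plus light 1 and 5 without light damage 7, and DESeq2 called 85 genes and limma-voom 37.

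Nanoceria plus light against vehicle plus light, 5 libraries each, asks directly whether the particles alter the retina exposed to light. No named photoreceptor, glial, cytokine or antioxidant gene passed: Gnat1 differed by 0.43 ± 0.39, Opn1sw by -0.07 ± 0.38, Gfap by -0.0034 ± 0.50, Edn2 by 0.08 ± 0.37, Ccl2 by -0.52 ± 0.37, C3 by 0.09 ± 0.47, Hmox1 by -0.05 ± 0.35, Sod2 by 0.0018 ± 0.15 and Fgf2 by 0.30 ± 0.17. Those for Gfap, Edn2, Hmox1 and Sod2 lay so near 0 that their sign changed with the tool, the scaling or a covariate. The 5 genes with the smallest p were Rptn (-6.69 ± 1.62) and Matn1 (6.55 ± 1.95), of the epidermis and of cartilage matrix, Mettl7b (-5.67 ± 1.54), Ly6al (4.12 ± 1.26) and the potassium channel Kcnj8 (0.59 ± 0.18), all at an edgeR adjusted p of 1. Chemokine and cytokine genes had a median of -0.29, immediate early genes of -0.16 and nuclear encoded oxidative phosphorylation genes of 0.07, each past the threshold at the preset correlation (adjusted p = 0.96 with an estimated correlation for all 3), and no list had a called member, adjusted over the list alone or over all genes. The sign of Rptn reversed with limma-voom. Rptn (1.44 ± 3.20 CPM, SD, n = 5), Mettl7b (0.89 ± 1.94 CPM) in vehicle plus light and Ly6al (1.63 ± 3.37 CPM) in nanoceria plus light had an SD above their mean.

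edgeR called 0 genes between nanoceria plus light and vehicle plus light, with 257 at an unadjusted p under 0.05, fewer than the 905 that chance gives, and limma-voom called 0. DESeq2 called 4, Hsp90aa1, LOC100909505, NEWGENE_1304700 and Hprt1, named after their values were seen, each listed at 0 in all nanoceria plus light libraries. The count by edgeR stayed 0 without any 1 of the 10 libraries.

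Whether the response to light differed between nanoceria and vehicle was tested as an interaction. The genes with the smallest p were Vrtn (2.696 ± 0.71), Chi3l1 (-1.51 ± 0.41), Cd84 (-1.2504 ± 0.34), Nog (-1.76 ± 0.48) and the leukocyte adaptor Fyb (-0.90 ± 0.25), all at an edgeR adjusted p of 1, as were Ccl2 (-0.81 ± 0.56) and C3 (-1.56 ± 0.69). The T and B lymphocyte list had a median of -0.87 (adjusted p = 0.0288 with an estimated correlation, fry adjusted p = 0.209), the microglia and macrophage list of -0.57 (adjusted p = 0.132 with an estimated correlation) and the vascular list of -0.35 (adjusted p = 0.0741 with an estimated correlation). By mean log2 CPM, nanoceria lay above vehicle without light by 0.755, 0.454 and 0.368 for these lists, in that order. With light the differences were -0.209, -0.0366 and -0.0191. None passed when adjusted over the 84 list tests. These negative values thus lie mostly in the groups without light. Chi3l1, Cd84 and Nog were also higher in nanoceria than in vehicle without light, as given above, though not called. edgeR called 0 genes, with 415 at an unadjusted p under 0.05 and 905 expected by chance; DESeq2 called 1, LOC691162, and limma-voom 0.

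The response to light after vehicle was also compared with that without injection. As the change after vehicle minus that without injection, the difference was negative for the chemokine genes Ccl3 (-2.35 ± 0.46) and Cxcl11 (-2.48 ± 0.46) and for Cntnap5b, a cell adhesion gene (-2.64 ± 0.39), and positive for Etv4 (1.14 ± 0.19), Spice1 (0.60 ± 0.10), LOC100359600 (1.15 ± 0.22) and AABR07017268.1 (1.84 ± 0.27). Ccl3 and Cxcl11 rose in both, by less after vehicle (3.58 ± 0.34 and 2.07 ± 0.32) than without injection (5.93 ± 0.38 and 4.55 ± 0.36). Cntnap5b rose without injection (0.85 ± 0.26) and fell after vehicle (-1.79 ± 0.29). AABR07017268.1 fell without injection (-0.56 ± 0.18) and rose after vehicle (1.29 ± 0.20). Etv4 rose after vehicle (0.96 ± 0.14) and was -0.17 ± 0.13 without injection (edgeR adjusted p = 0.369). The groups without light also differed: Etv4 was lower in vehicle than in control, as given above. Cxcl11 was higher in vehicle than in control by 2.03 with the replicate number as a block (edgeR adjusted p = 0.0289), though not called in the main fit. By these values most of the difference for Etv4, and much of that for Cxcl11, lies in the groups without light. LOC100359600 and Spice1 fell without injection (-1.03 ± 0.15 and -0.39 ± 0.07), and after vehicle were 0.12 ± 0.16 and 0.22 ± 0.08 (edgeR adjusted p = 0.705 and 0.0522). Plscr5 had a negative difference too, but was listed at 0 in every control library, so no fold is given. LOC100359600 and AABR07017268.1 were named after their values were seen. These are the 4 higher and 4 lower calls of edgeR (1059 genes at an unadjusted p under 0.05; DESeq2 41, limma-voom 118). Of 26 chemokine and cytokine genes 2 were lower (5 adjusted over the list alone; adjusted p = 0.282 with an estimated correlation). The number of calls was 21 without vehicle 1 and 5 without control 5, light damage 6, vehicle 2 or vehicle 4. The call of Ccl3 (edgeR adjusted p = 0.0438) ended without any of 15 single libraries (up to 0.154, without vehicle 3). That of LOC100359600 ended without any of 16 (up to 0.113, without control 6). That of Cxcl11 ended without any of 9 (up to 0.103, without control 5) and that of Spice1 without control 6 (0.0562), with library size alone or on the groups compared alone. With a replicate number left out of every group, Spice1 did not pass without 1, 2, 3, 5 or 6 (up to 0.105). Nor did Plscr5 without 2, 3, 5 or 6 (up to 0.132) or Etv4 without 2, 3 or 4 (up to 0.0743). Ccl2 did not pass (-1.80 ± 0.54, edgeR adjusted p = 0.422).

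**Figure D2:**
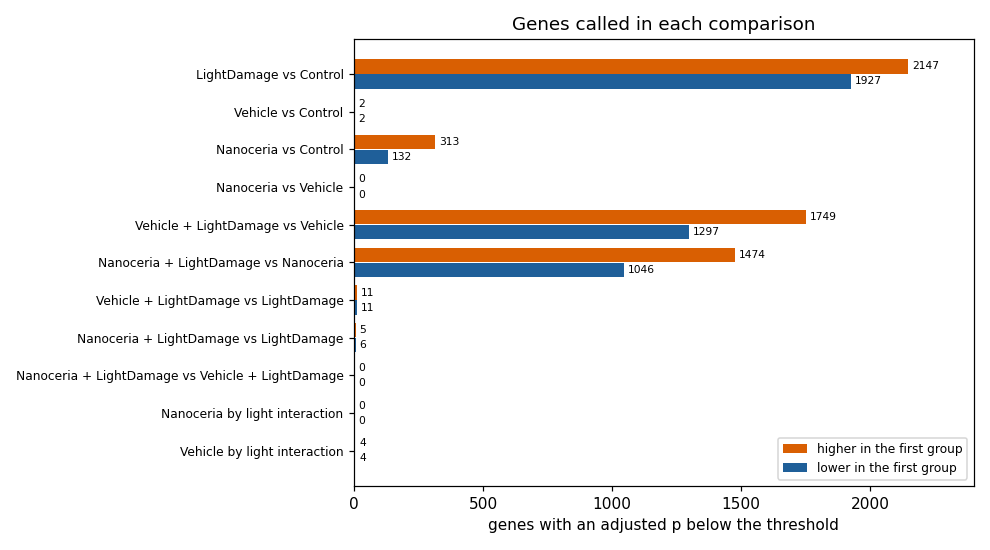
Number of genes (x axis) called higher (orange) and lower (blue) by edgeR in each comparison (y axis). The 3 responses to light hold 4074, 3046 and 2520 genes, and nanoceria plus light against vehicle plus light holds 0.

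A light response score of 584 raised and 213 lowered genes, chosen on control and light damage alone, put every light-exposed group above its own control. Its mean was -1.90 ± 0.245 (SD, n = 5) in control, 1.36 ± 0.474 (n = 7) in light damage, -1.52 ± 0.103 (n = 5) in vehicle, 0.92 ± 0.616 (n = 5) in vehicle plus light, -1.25 ± 0.177 (n = 4) in nanoceria and 0.89 ± 0.548 (n = 5) in nanoceria plus light. The shift with light was 3.25 without injection, in the samples that chose the genes, 2.44 after vehicle (95% interval 1.76 to 3, exact permutation p = 0.00794, the smallest it can give, adjusted p = 0.0198) and 2.15 after nanoceria (1.5 to 2.86, exact permutation p = 0.00794, also the smallest, adjusted p = 0.0198). Nanoceria plus light and vehicle plus light differed by -0.03 (95% interval -0.87 to 0.88, exact permutation p = 0.96), less than the spread between replicates. Without light, nanoceria lay above vehicle by 0.27 (0.04 to 0.49, exact permutation p = 0.0397, adjusted p = 0.0661), which does not pass. That test, like the other score tests, counted the near-identical vehicle 4 and vehicle 7 (-1.616 and -1.598) as separate libraries. Its interval and the SD of vehicle may therefore be too narrow. The interaction of nanoceria with light was -0.30 (permutation p = 0.438, adjusted p = 0.548).

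The rod score, the mean log2 CPM of the rod genes, fell by 1.37 with light alone (95% interval -1.82 to -0.93, exact permutation p = 0.00126, the smallest it can give, adjusted p = 0.0114), by 1.45 after vehicle (-1.96 to -0.86, exact permutation p = 0.00794, again the smallest, adjusted p = 0.0357) and by 1.49 after nanoceria (-2.64 to -0.62, exact permutation p = 0.0159, adjusted p = 0.0476). Nanoceria plus light and vehicle plus light differed in it by -0.10 (-1.09 to 0.9, exact permutation p = 0.881), an interval that leaves room for changes of up to about 1 in either direction. The other 5 comparisons, of groups without light or of light-exposed groups with and without injection, lay between -0.07 and 0.19 and none passed (exact permutation, adjusted p of at least 0.393).

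**Figure D3:**
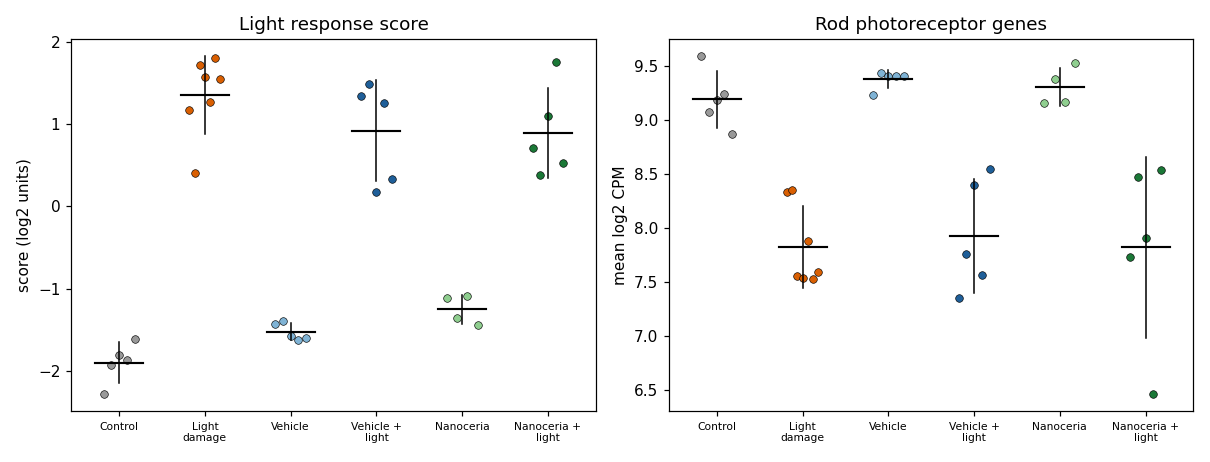
Light response score and rod score (both on the log2 scale) of each library (points) by group, with mean (horizontal line) and SD (vertical line). The nanoceria plus light and vehicle plus light libraries overlap in both scores.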

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

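Leaving out single libraries was chosen after the results below were seen. In 84 tests, of 14 measures in each of 6 groups of 4, 5 or 7 libraries, 5 found a library far from the others by Dixon's test at 95%, and chance gives about 1 in 20, 4.2 here. No explanation was weighed for these.

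Light damage 1 had the lowest total of its group, 25.2 M counts against 107 M to 149 M, and the largest share of counts in features named like ribosomal RNA and repeats, 19.6% against 0.21% to 0.512%. Without this library light damage against control had 3929 calls in place of 4074. Vehicle 1 had a rod score of 9.23 against 9.40 to 9.43 in the other vehicle libraries, and its Sod2 level was 7.06 (log2 CPM) against 6.74 to 6.78. Control 6 had a Sod2 level of 6.95 against 6.89 to 6.90 in the other control libraries.

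The response to light differed between vehicle and no injection, by the test of the interaction, in 8 genes. The differences, as log2 fold changes of the response after vehicle against that without injection, were -2.64 for Cntnap5b, 1.84 for AABR07017268.1, 1.14 for Etv4, 0.603 for Spice1, -2.48 for Cxcl11, 1.15 for LOC100359600 and -2.35 for Ccl3. Most of that for Etv4, and much of that for Cxcl11, lies in the groups without light, as given above. The fitted value of Plscr5 was -9.08, but this gene had 0 counts in every control library, so the value rests on the prior count and is no measure of size. Without vehicle 1 the number of such genes was 21. With libraries or a replicate number left out it ranged from 2 to 21, and with the near-identical pairs summed it was 5. Chance is not excluded for this number, as given below.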

How the results depend on the processing

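Leaving out 1 library at a time, summing the near-identical pairs, limma-voom on those sums and the term for sex were chosen after seeing the data; the other alternatives were chosen before. The calls of light damage against control kept within 1.5 times of 4074 under every alternative run (3256 to 4167 with libraries or a replicate number left out). Of 4945 alternative values of the 175 named gene values, 4458 kept their direction and their side of the threshold, 387 lost the call, 43 gained it and 57 changed direction. None of the 127 called values changed direction. Unless a reason is given, the cause of a difference was not tested.

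Counts moved by more than 1.5 times both with the tool and with libraries left out. limma-voom called 2211 genes for vehicle against control, 1276 for nanoceria against control, 1493 for nanoceria against vehicle, 5219 for vehicle plus light against vehicle, 229 for vehicle plus light against light damage, 37 for nanoceria plus light against light damage and 118 for the interaction of vehicle with light. Its weights were 4.83 for vehicle 4 and 3.3 for vehicle 7, 2 near-identical libraries, against 0.349 to 2.76 for the rest. With the near-identical pairs summed, these 7 counts were 12, 1192, 0, 3150, 42, 7 and 14, so much of the excess for vehicle against control, nanoceria against vehicle and vehicle plus light against vehicle rests on the near-identical pairs. DESeq2 called 51, 713 and 35 genes for the first 3 of these, 92 and 85 for the 2 injected light groups against light damage, 4 for nanoceria plus light against vehicle plus light, 1 for the interaction of nanoceria with light and 41 for that of vehicle with light. Fitted on the groups compared alone, with fewer samples to estimate the spread, edgeR called 0 for vehicle against control, 1107 for nanoceria plus light against nanoceria and 5 for nanoceria plus light against light damage. With the near-identical pairs summed it called 7 for nanoceria plus light against light damage and 5 for the interaction of vehicle with light, and with a term for sex 1 for vehicle against control.

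With libraries or a replicate number left out, the counts ranged from 1 to 24 for vehicle against control, 44 to 432 for nanoceria against control, 0 to 13 for nanoceria against vehicle, 1825 to 3206 for vehicle plus light against vehicle, 1609 to 3052 for nanoceria plus light against nanoceria, 7 to 30 for vehicle plus light against light damage, 3 to 47 for nanoceria plus light against light damage, 0 to 1 for the interaction of nanoceria with light and 2 to 21 for that of vehicle with light. For nanoceria plus light against vehicle plus light every such fit called 0 genes. The lowest for nanoceria against control, 44, followed the removal of replicate 1 from all groups.

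Numbers of gene lists past the threshold fell when camera estimated the correlation between genes, from 19 to 2 for light damage against control, 20 to 2 for vehicle plus light against vehicle, 18 to 2 for nanoceria plus light against nanoceria, 15 to 0 for vehicle against control, 14 to 4 for nanoceria against control, 16 to 2 for nanoceria against vehicle, 13 to 0 and 8 to 0 for the injected light groups against light damage, 4 to 0 for nanoceria plus light against vehicle plus light, 13 to 1 for the interaction of nanoceria with light and 12 to 0 for that of vehicle with light. Fry found 8 for nanoceria against control and 0 for the other 7 comparisons without a light response.

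The rod score of nanoceria plus light against nanoceria was -1.44 with library size alone (adjusted p = 0.0714) and that of nanoceria plus light against light damage changed sign, to 0.0329, as did the light response score of nanoceria plus light against vehicle plus light with the median over genes, to 0.00492. With a replicate number left out, the light response score ranged from 2.33 to 2.61 for vehicle plus light against vehicle, 1.93 to 2.24 for nanoceria plus light against nanoceria, 0.205 to 0.338 for nanoceria against vehicle (0.334 without replicate 5, adjusted p = 0.0446), -0.262 to 0.244 for nanoceria plus light against vehicle plus light and -0.466 to -0.0936 for the interaction of nanoceria with light. The rod score ranged from -1.61 to -1.35 and -1.63 to -1.15 for the first 2 of these, -0.305 to 0.147 for nanoceria plus light against vehicle plus light, -0.0974 to 0.334 for vehicle plus light against light damage and -0.174 to 0.289 for nanoceria plus light against light damage. The rod response after nanoceria did not pass in 6 of 7 such fits, and the rod response after vehicle and the light response score after vehicle and after nanoceria in 4 of 7 each. Fewer libraries make the smallest exact p larger.

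The genes that changed direction were not called, and all are of nanoceria plus light against vehicle plus light; all but Rptn (-6.69) lay near 0. With limma-voom Rptn was 0.139, Edn2 -0.173 and Hmox1 0.0679, and on the summed pairs 0.132, -0.167 and 0.064. Sod2 was -0.0162 with either use of the size factors of DESeq2, -0.00815 with library size alone, -0.000885 without the filter and -0.011 on the 2 groups alone. Gfap was 0.00233 with the term for sex. With libraries left out, Rptn ranged from -7.17 to 0.594, Opn1sw from -0.574 to 0.365, Gfap from -0.156 to 0.128, Edn2 from -0.0817 to 0.387, C3 from -0.123 to 0.448, Hmox1 from -0.494 to 0.304 and Sod2 from -0.207 to 0.192.

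Replicate numbers were not taken to pair the libraries, since the labels tie them to no shared animal, litter or day. By the values below, libraries of equal number in different groups were nonetheless more alike than those of different number. Shared handling may be a cause, which was not tested, and the main fits hold no term for it. Of 60 pairs of equal number in different groups, 23 had a correlation of deviations from the group means above 0.1. The median was 0.078 (-0.353 to 0.381) against -0.00581 for different numbers. Of 31 libraries, 12 correlated best with their own number, where chance gives 4.67. Each of the 7 numbers runs over consecutive numbers of the library names, 1 to 6 for replicate 1 and 30 or above for the rest. With the replicate block, edgeR called 184 genes for nanoceria against control and 5 for the interaction of vehicle with light. For nanoceria plus light against vehicle plus light, 8 gene lists passed at the preset correlation of camera, against 4 without the block. At an estimated correlation 0 passed without the block, and that setting was not run with the block. Named genes that lost their call with the block follow, with their edgeR adjusted p in brackets. In nanoceria against control these were Csf3r (0.0528), Cd3e (0.0556), Mthfd2 (0.0509) and Vwf (0.13). In the interaction of vehicle with light they were Etv4, Ccl3 and Plscr5 (each 0.0557) and LOC100359600 (0.161). C3 (0.0607) lost it in light damage against control, and Actg2 (0.0863) and LOC497796 (0.0629) in vehicle against control. So did Cryga (0.105) and Mip (0.0902) in vehicle plus light against vehicle, and RT1-CE3 (0.0678) and Slc27a1 (0.0769) in nanoceria plus light against light damage. Sod2 was -0.0354 for nanoceria plus light against vehicle plus light. The light response score was 2.57 after vehicle and 1.93 after nanoceria (adjusted p = 0.25), and the rod score -1.27 without injection, -1.6 after vehicle and -1.15 after nanoceria (adjusted p = 0.375), with too few pairs to pass.

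The depth, 25158407 counts in light damage 1 and at least 73369026 in the other libraries, limits the genes of low level most.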

Other observations

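The tests of the immune genes with nanoceria, the test of a difference between the animals, the test of tissue outside the retina, the splits of nanoceria plus light against vehicle plus light, the splits with the near-identical pairs summed and the spread over left-out libraries were chosen after the results were seen; the other tests here were chosen before.

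Immune cell lists were higher in nanoceria than in control, though none of the list tests in this paragraph passes when adjusted over the 84 run. The mean log2 CPM of the microglia and macrophage list was higher by 0.77 (95% interval 0.41 to 1.1, exact permutation p = 0.00794, the smallest it can give, adjusted 0.0741) and that of vehicle was higher than control by 0.31 (0.02 to 0.58, exact permutation p = 0.0159, adjusted 0.0954). The injection without the particles may account for part of the pattern: nanoceria lay above vehicle by 0.45 (0.16 to 0.73, exact permutation p = 0.0238, adjusted 0.105), but with the near-identical vehicle pair averaged the exact permutation p was 0.0571, and the neutrophil list lay above control by 0.96 in vehicle and by 1.32 in nanoceria (both exact permutation p = 0.00794, adjusted 0.0741), with nanoceria above vehicle by 0.36 (-0.41 to 1.08, exact permutation p = 0.302). The T and B lymphocyte list lay above control by 0.41 in vehicle and by 1.16 in nanoceria, with nanoceria above vehicle by 0.76 (0.2 to 1.35, exact permutation p = 0.0238, and 0.0571 with the pair averaged), and the complement list by 0.38 and 0.76, with 0.38 between them (-0.06 to 0.79, exact permutation p = 0.0714). More sclera and choroid tissue stays open too: the upper bound of the difference of its own markers was 0.29, below 0.77, but these are abundant in control (mean log2 CPM 8.09, against 3.91 for the microglia and macrophage list), and the vascular list, whose cells the choroid also carries, was higher in nanoceria than in control by 0.36 (0.16 to 0.54, exact permutation p = 0.0159, adjusted 0.0954). So does more blood, since the upper bound for the blood list was 0.97. A response to the particles remains open as a hypothesis.

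Between the injected and the uninjected groups under light, 25 genes were called in either of the comparisons, which share the light damage libraries. An effect of the injection that does not need light may account for some. Of the 25, 24% (6 genes, 95% exact binomial interval 9.36% to 45.1%) differed the same way at an unadjusted p under 0.05 in vehicle or nanoceria against control. The bound set before the test was 25%, and the share lay under it by less than its spread, so this stays open. A genetic or cohort difference between the animals also stays open: 1 of the 25 genes was switched on and off (over a range of more than 4 on the log2 scale) within control, vehicle or nanoceria, and 38.5% of 10000 sets of random genes of equal expression held as many. A response to light that the injection changes was tested only through the interaction given above.

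Nanoceria plus light against vehicle plus light gave fewer small p-values than chance, which may be a sign that libraries vary within the groups along something the groups share, though no test here established this. Fitted on these 10 libraries, 126 genes were at an unadjusted p under 0.05, where chance gives 869, and without nanoceria plus light 5 there were 304. Differing responses to light within both groups may be a cause: with the light response score as a term the number was 164, 1.3 times as many (0.971 to 1.5 with 1 library left out at a time). With sex as a term it was 115 (0.913 times, 0.761 to 1.69), and with the first component of the 7 lists of tissue outside the retina 137 (1.09 times, 0.868 to 2.26). An explanation needed at least 2 times as many. Even that would stay under the number that chance gives, so reaching it could not account for the whole shortfall. A bound between 1 and 2 times, under which an explanation would be argued against, was set with the tests. Sex and tissue lay under that bound with all libraries but passed it without some single library, and the light response score lay between the bounds, so these 3 cannot be told apart. No biological explanation was tested beyond these.

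Each count of called genes was set against 100 splits of the same libraries into groups of the same sizes, the real one included. Chance can be excluded for light damage against control (4074 calls, 3258 in the highest other split), vehicle plus light against vehicle (3046, 905) and nanoceria plus light against nanoceria (2520, 2839). For these, 1, 1 and 2 splits were as large by calls, and 1, 1 and 4 by the number of genes at an unadjusted p under 0.05. Few splits had as many calls for nanoceria against control (445, 103), vehicle plus light against light damage (22, 13), vehicle against control (4, 125) and the interaction of vehicle with light (8, 355), with 1, 1, 2 and 3 as large. By unadjusted p, however, 7, 13, 17 and 35 splits were as large, so chance is not excluded for these 4. With each near-identical pair of libraries summed to 1, so that no split can part it, the real counts were 3548, 2403, 2332, 391, 15, 3 and 5 and the highest in 99 other splits 2417, 1757, 1366, 63, 5, 1 and 2, so 1 split was as large in each, while by unadjusted p 1, 1, 3, 7, 13, 39 and 49 were. By calls as well, chance cannot be excluded for nanoceria plus light against light damage (11, 56), where 14 splits were as large (10 with the pairs summed). For nanoceria against vehicle (0, 3 in the highest other split), nanoceria plus light against vehicle plus light (0, 1114) and the interaction of nanoceria with light (0, 19) all 100 splits are as large whatever the data, so the test decides nothing. Splits that call many genes, several times the real count, point to a structure of the samples. For vehicle against control the split with 125 calls set control 1 and 4 with vehicle 1, 2 and 3 against the other 5, which hold the near-identical pair. For nanoceria plus light against vehicle plus light the split with 1114 calls set vehicle plus light 1, 2 and 6 with nanoceria plus light 2 and 5 against the other 5. On the second principal component the first 5 lay at 7.42 to 63.73 and the other 5 at -40.28 to -4.57. Their light response scores overlapped (mean 0.816, from 0.33 to 1.49, against 0.998, from 0.178 to 1.75). What that component reflects was not tested. The splits with 56 and 355 calls also point to such a structure.

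Near-identical libraries were found in 2 groups. Over genes with at least 20 counts, the median squared difference between vehicle 4 and vehicle 7 was 2.46 times what counting alone gives, and between light damage 4 and light damage 7 it was 3.75 times, while the next lowest of 465 pairs had 12.2 and the median pair 44.4. In both groups the pair was replicate 4 with replicate 7. They were kept as separate libraries, as the labels list them, so SE, SD and p-values of these groups may be too small. With each pair summed, edgeR called 3548 genes in place of 4074 for light damage against control. It called 2403 in place of 3046 for vehicle plus light against vehicle, and 15 in place of 22 for vehicle plus light against light damage. Further effects of summing are given with the processing. Whether a pair comes from 1 animal or is 1 sample measured again is not known.

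Lens markers held 0.345% of the counts in control, 1.42% in vehicle, 0.532% in vehicle plus light, 0.506% in nanoceria, 0.463% in nanoceria plus light and 0.469% in light damage. Single libraries carry part of this: control held 0.209% without control 5, vehicle 0.914% without vehicle 1 and nanoceria 0.199% without nanoceria 1. By mean log2 CPM of the list, vehicle lay above control by 2.16 (exact permutation p = 0.0556). The vascular list was higher in nanoceria than in vehicle by 0.37 (exact permutation p = 0.0159, adjusted over 84 tests 0.0954, which does not pass; 0.0286 with the near-identical vehicle pair averaged). Y-linked transcripts split the 31 libraries into 16 high and 15 low, and 5 of the low ones held 2.46% to 5.7% of the mean of the high ones for Ddx3 and Eif2s3y and 6.78% to 8.68% for Kdm5d, for which the other low ones held 2.31% to 4.48%. Nanoceria plus light 4 had the lowest rod score of all libraries, 6.46.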
